A study of Oryctolagus cuniculus with 34 samples.

How the data were processed

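The data are 34 libraries of rabbit supraspinatus muscle, 1 library per file. RNA extraction and library construction were done by a commercial laboratory, per the labels' protocols. The authors deposited raw read counts per gene, whole numbers with no normalization. STAR, edgeR and the build OryCun2.0 are named in the submitters' processing notes. Their versions, the counting tool, the annotation and the use of strand are not given in the sources used here, so genes that overlap or have near-identical copies cannot be told apart.

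Each file held 18210 gene entries. In all, 26 entries whose names had been turned into dates were left out, at most 0.163% of a library, and 15 entries of 7 repeated symbols were summed, leaving 18176 genes. Of 3500 LOC identifiers, 2379 matched a RefSeq table of another rabbit assembly by gene number and 578 received a symbol. That table was used for names only, so no coordinates, gene lengths or GC content are given. Identical or near-identical libraries were sought among 91 pairs within groups. There were 0 identical pairs, and the lowest chi-square per degree of freedom was 10.4, where sampling noise alone gives about 1.

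Groups and replicate numbers came from the sample titles. The labels do not state that the libraries of a group came from separate animals, though the animal codes in the files' names differ within each group. If these codes are animals, p-values measure the spread between animals, which may in part be technical. The animal codes in the files' names link each long-term operated muscle to an uninjured one. They were treated as a pairing: over genes chosen without the animal in question, the uninjured library of the same code was the best match for 9 of 10 operated libraries (over all genes, by correlation of deviations, for 4 of 10), and 39 genes had a Spearman rho above 0.9 across the 10 animals, against a median of 3 over 1000 random pairings, of which 3 gave as many. By Pearson correlation the pairing did not stand out: 28 genes had an r above 0.9, and 9 of 100 random pairings gave as many, the largest 82. These correlations of deviations exceeded 0.1 in 6 of the 10 pairs, with a range of -0.262 to 0.382.

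Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filtering by expression, robust quasi-likelihood test), limma 3.58.1 and, as an alternative, DESeq2 1.42.0. The 14 short-term libraries were fitted together (13526 genes), as were the 20 long-term libraries (11605 genes) and, for the comparisons between terms, all 34 (12935 genes). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, from 2-sided tests. Log2 differences are fitted, first group minus second, with their standard errors. Log2 CPM values used a prior count of 2.

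The groups compared, tests, alternatives, 30 gene lists, a panel of 27 genes and the rule for named genes were fixed before the data were examined. Lists with 5 or more genes tested were tested with camera at its preset correlation of 0.01, and again with an estimated correlation, with fry and with an exact permutation test of list scores. The list of mitochondrially encoded genes had 0 genes in the files. The rule named the panel, the 5 genes with the largest rise and fall past the threshold with a symbol, a mean log2 CPM of at least 1 and groups that do not overlap (or, where nothing passed, the 5 with the smallest p), and up to 3 members per list and direction past the threshold. Which panel genes are given singly in each comparison was decided after their values were seen and by no fixed rule. Some genes left out lay further from 0 than some given. The number and range of the rest are given instead.

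The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For gel against repair 22% and 67% were recovered in the short term, with 2 false calls, and 60% and 98% in the long term, with 7. For repair against injury these were 20% and 61%, with 3, and for gel against injury 17% and 68%, with 5. Repair against uninjured muscle gave 70% and 99%, with 2, and gel against uninjured muscle 76% and 98%, with 7.

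Alternatives were DESeq2, its size factors, limma voom with sample quality weights, no filter on low counts, erythroid genes left out, only the groups compared, all libraries in one fit, replicate blocks, and each replicate left out. Alternatives chosen after seeing the data left out libraries that lie apart from their groups, or used the animal as a random effect. Outlying libraries were sought for every list, for the whole panel and for the other named genes.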

Results

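Gene expression was measured by bulk RNA sequencing in the supraspinatus, a rotator cuff muscle of the shoulder, of rabbits. In the short term 5 muscles had a repair only, 5 had a repair with a gel made from tissue-derived extracellular matrix, and 4 had the injury only. In the long term 5 muscles had a repair only, 5 had the repair with the gel, and 10 were uninjured. The deposited values were raw read counts per gene, with totals of 26904529 to 32313295 counts in the 14 short-term libraries and 12582302 to 15019158 in the 20 long-term libraries. Between 13927 and 15204 genes had at least 1 count in a short-term library, and between 13603 and 14433 in a long-term library.

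**Figure D1:**
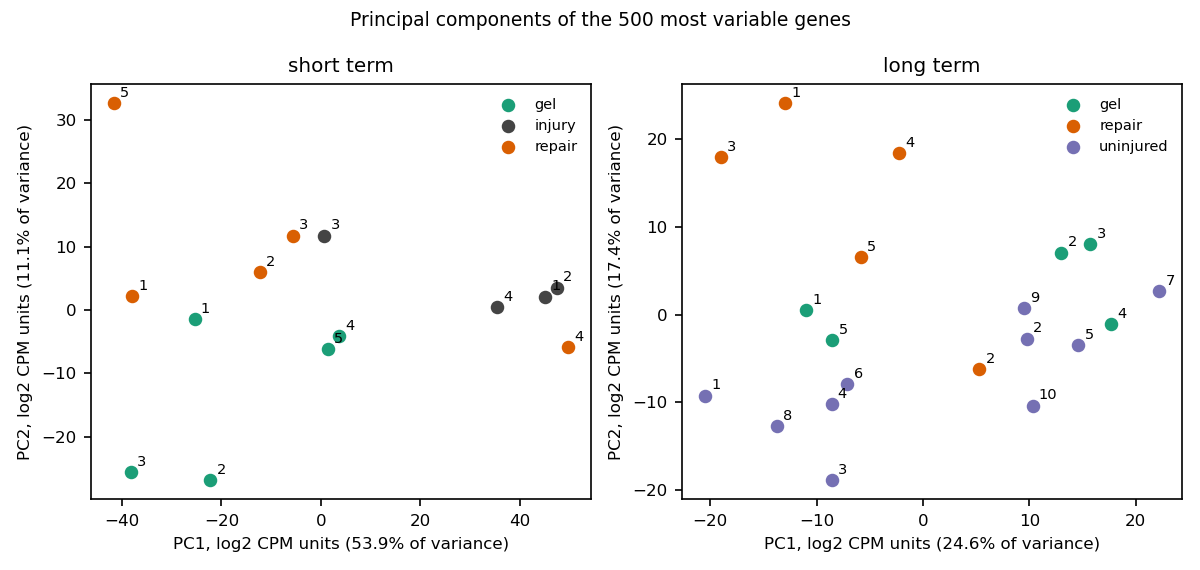
Principal components of log2 CPM over the 500 most variable genes, short term on the left and long term on the right, 1 point per library with its replicate number. On the first component of the short term (53.9% of the variance) repair replicate 4 lies at 49.7, beside injury replicates 1, 2 and 4 (45, 47.4 and 35.4), and injury replicate 3 lies at 0.681.

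The first comparison asked what the gel added to a repair in the short term (5 libraries against 5). Oxidative phosphorylation genes, which encode the respiratory chain, had a median log2 difference of 0.64, with 31 of 31 members above 0, and citric acid cycle and fatty acid oxidation genes one of 0.55, with 28 of 28 above 0. Slow fibre genes (median 1.40, 10 of 10 above 0) and developmental sarcomere genes (1.82, 9 of 9) were also higher with the gel. Fibrillar collagens and fibrosis genes were lower (-1.57, 26 of 26 below 0), as were tenocyte markers (-1.18, 9 of 9), TGF-beta signalling genes (-0.55, 15 of 20) and atrophy genes (-0.33, 13 of 14). T and B lymphocyte markers (1.21) and interferon response genes (0.94) completed the 10 of 28 lists past the threshold of the camera test with its preset correlation, 6 higher and 4 lower. Other splits of these libraries into groups of 5 passed lists as well, with a median of 12 and at least 1 list in 99 of them. In the 5 comparisons that follow, such splits gave medians of 13, 12, 5, 8 and 5 lists. Lists past this test are therefore not by themselves evidence of a treatment effect.

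None of these 10 lists passed with an estimated correlation: the adjusted p was 0.412 for the oxidative phosphorylation, citric acid cycle, slow fibre, developmental sarcomere, TGF-beta and atrophy lists, 0.599 for the lymphocyte list and 0.633 for the collagen, tenocyte and interferon lists. Adjusted over the list alone, 5 citric acid cycle and fatty acid oxidation genes and 4 slow fibre genes were higher, as was 1 gene each of the lymphocyte, fibroblast and pro-inflammatory cytokine lists. Over all 13526 genes, edgeR's quasi-likelihood test called 0 genes, with 1404 at an unadjusted p under 0.05. DESeq2 called 127, and limma voom with sample quality weights called 3.

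The genes with the smallest p were PPIF, a regulator of the mitochondrial permeability pore (log2 difference 1.49, SE 0.22), ATXN7L2, a member of the ataxin 7 family (1.98, SE 0.30), FUOM, a fucose mutarotase (0.81, SE 0.13), and FAM206A (0.97, SE 0.15), each at an edgeR adjusted p of 0.0654. DBI, the acyl-CoA binding protein, was next (0.98, SE 0.19, adjusted p 0.369). PPIF averaged 46 ± 11.3 CPM with the gel and 16.4 ± 5.13 CPM with repair alone (SD, n = 5 each). Of the fixed panel, 0 of 22 genes tested passed. The collagen genes COL1A1 (-2.37, SE 1.11) and COL3A1 (-1.92, SE 0.86), the fibro-adipogenic progenitor marker PDGFRA (-1.15, SE 0.50), the proteoglycan gene DCN (-0.91, SE 0.38) and the macrophage scavenger receptor CD163 (-1.51, SE 0.89) had lower fitted values with the gel. The embryonic myosin MYH3 (3.19, SE 1.09), the satellite cell regulator PAX7 (0.92, SE 0.44), the mitochondrial coactivator PPARGC1A (0.86, SE 0.43) and the proliferation marker MKI67 (0.55, SE 0.79) had higher ones. The ubiquitin ligases of muscle atrophy FBXO32 and TRIM63 had values of -0.90 (SE 0.49) and -0.48 (SE 0.30). Single libraries moved several of these: without repair replicate 5 COL1A1 was -0.79 and COL3A1 -0.73, without repair replicate 1 CD163 was -0.40, and without gel replicate 3 MYH3 was 1.71 and PAX7 0.385. PPARGC1A was 0.392 without gel replicate 4, TRIM63 -0.258 without repair replicate 3, and MKI67 ranged from 0.244 without repair replicate 4 to 1.44 without repair replicate 5. The other 11 panel genes lay between -1.97 and 0.26, with a lowest adjusted p of 0.518. Without repair replicate 2 the count was 2. Without injury replicate 3 and repair replicate 4, which lie apart from their groups, it was 13.

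The next comparison set repair against injury alone in the short term (5 against 4 libraries). Matrix genes were higher after repair: fibrillar collagens and fibrosis genes had a median log2 difference of 2.45 (26 of 26 above 0), matrix proteases 1.71 (17 of 19), basement membrane genes 0.51 (13 of 14) and TGF-beta signalling genes 0.56 (17 of 20). So were macrophage and monocyte markers (1.71, 17 of 17), alternative macrophage genes (1.67, 13 of 13), neutrophil and mast cell markers (1.15, 8 of 8) and cell cycle genes (2.00, 22 of 24). Fibro-adipogenic progenitor markers (0.88), denervation genes (1.36), cartilage and bone genes (1.93) and immediate early genes (0.79) were higher as well. Adipocyte genes (-1.59, 14 of 15 below 0), slow fibre genes (-1.74, 10 of 10), fast fibre genes (-1.01, 12 of 12), glycolysis genes (-0.999, 18 of 20), oxidative phosphorylation genes (-0.56, 31 of 31), citric acid cycle genes (-0.54, 26 of 28) and Schwann cell markers (-0.94, 12 of 12) were lower.

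These were 19 of 28 lists by camera with its preset correlation, 12 higher and 7 lower. With an estimated correlation 0 passed, the adjusted p being 0.448 for the fibro-adipogenic list and 0.356 for the other 18. Adjusted over the list alone, 13 collagen and fibrosis genes, 12 cell cycle genes, 6 matrix protease genes and 5 denervation genes were higher, and 6 slow fibre genes were lower. Over all 13526 genes edgeR called 0, with 1973 at an unadjusted p under 0.05 and a smallest adjusted p of 0.322. DESeq2 called 242 genes and limma voom with sample quality weights 4692.

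By smallest p the leading genes were the potassium channel gene KCNN3 (1.63, SE 0.28), the immediate early gene IER2 (1.49, SE 0.28), the muscle methyltransferase gene METTL21C (-4.38, SE 0.84), the phosphodiesterase gene PDE4B (1.04, SE 0.20) and the transporter gene ABCC5 (2.53, SE 0.50). METTL21C averaged 9.68 ± 9.74 CPM after repair (SD, n = 5) and 201 ± 98.7 CPM after injury alone (SD, n = 4). Of 22 panel genes 0 passed. Fitted values were 4.12 (SE 1.32) for COL1A1, 2.78 (SE 0.97) for COL3A1, 1.59 (SE 1.32) for the matricellular gene POSTN, 1.28 (SE 0.61) for TGFB1 and 1.17 (SE 0.54) for PDGFRA. Macrophage genes gave 3.32 (SE 1.06) for CD163, 4.30 (SE 1.27) for the arginase gene ARG1 and 1.56 (SE 0.78) for the receptor gene CSF1R. MKI67 gave 2.89 (SE 0.95). Without injury replicate 3 POSTN was 4.94, COL1A1 5.56 and COL3A1 3.68, without repair replicate 5 these were 0.625, 2.53 and 1.56, and without repair replicate 1 ARG1 was 1.94. The adipocyte genes PPARG (-1.70, SE 0.65), ADIPOQ (-0.95, SE 0.52) and FABP4 (-1.44, SE 0.56) were below 0, and without injury replicate 3 they were -0.948, -0.398 and -1.02. The acetylcholine receptor gene CHRNA1 (1.69, SE 0.71) and the myogenic regulators MYOD1 (1.07, SE 0.56) and MYOG (0.66, SE 0.32) were above 0. MYOD1 was 0.397 without repair replicate 2, and without repair replicate 1 MYOG was 0.438 and CD163 2.19. PDGFRA was 1.76 and CSF1R 2.56 without injury replicate 3. The other 7 panel genes lay between -0.29 and 0.40. Without repair replicate 4 edgeR called 34 genes, and without both repair replicate 4 and injury replicate 3 it called 4556.

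Gel-treated repair was also set against injury alone in the short term (5 against 4 libraries). Immune lists were higher with the gel: interferon response genes had a median log2 difference of 2.27 (12 of 12 above 0), macrophage and monocyte markers 2.22 (17 of 17), T and B lymphocyte markers 1.91 (12 of 13), neutrophil and mast cell markers 1.85 (8 of 8), alternative macrophage genes 1.81 (11 of 13) and pro-inflammatory cytokines 1.5 (7 of 9). Cell cycle genes (2.02, 22 of 24), developmental sarcomere genes (2.46, 8 of 9), denervation genes (0.88), matrix proteases (1.10), cartilage and bone genes (1.44), collagens (0.69) and basement membrane genes (0.53) were higher too. Adipocyte genes (-1.29, 14 of 15 below 0), atrophy genes (-0.41), fast fibre genes (-0.67), glycolysis genes (-0.80) and Schwann cell markers (-0.84) were lower.

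These were 18 of 28 lists by camera with its preset correlation, 13 higher and 5 lower. With an estimated correlation 0 passed. The adjusted p was 0.453 for the lymphocyte and Schwann cell lists, 0.535 for basement membrane genes, 0.751 for collagens, matrix proteases, fast fibre and glycolysis genes, and 0.448 for the other 11. Adjusted over the list alone, 11 interferon response genes, 11 cell cycle genes, 6 macrophage markers and 4 pro-inflammatory genes were higher. Over all genes edgeR called 0, with 2493 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0522. DESeq2 called 788 and limma voom with sample quality weights 3776.

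The 3 genes at that adjusted p were ATXN7L2 (2.26, SE 0.33), the trophinin gene TRO (1.59, SE 0.24) and the preadipocyte factor gene DLK1 (4.55, SE 0.69). The histone chaperone gene ANP32E (-0.90, SE 0.15) and the Polycomb gene BMI1 (-1.04, SE 0.18) followed at 0.120. DLK1 averaged 2.75 ± 1.39 CPM with the gel (SD, n = 5) and 0.115 ± 0.0464 CPM after injury alone (SD, n = 4). Of 22 panel genes 0 passed. Fitted values were 3.44 (SE 0.97) for MKI67, 3.29 (SE 1.20) for MYH3, 1.76 (SE 1.18) for COL1A1, 0.86 (SE 0.90) for COL3A1 and 1.51 (SE 0.62) for TGFB1. CD163 gave 1.81 (SE 1.00), CSF1R 1.42 (SE 0.78), ARG1 2.33 (SE 1.22), CHRNA1 1.56 (SE 0.71) and MYOD1 1.33 (SE 0.56). PPARG (-1.74, SE 0.65), ADIPOQ (-1.14, SE 0.52), FABP4 (-1.29, SE 0.55) and FBXO32 (-0.78, SE 0.51) were below 0. Without injury replicate 3 COL1A1 was 3.21, COL3A1 1.77, CD163 2.96, CSF1R 2.43, PPARG -0.993 and ADIPOQ -0.584. Without gel replicate 3 MYH3 was 1.79, MYOD1 0.621 and TGFB1 0.911, and FBXO32 ranged from -1.18 without gel replicate 5 to -0.494 without injury replicate 1. The other 8 panel genes lay between -0.51 and 0.84. Without injury replicate 3 edgeR called 382 genes, without gel replicate 5 it called 2, and without both injury replicate 3 and repair replicate 4 it called 2577.

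**Figure D2:**
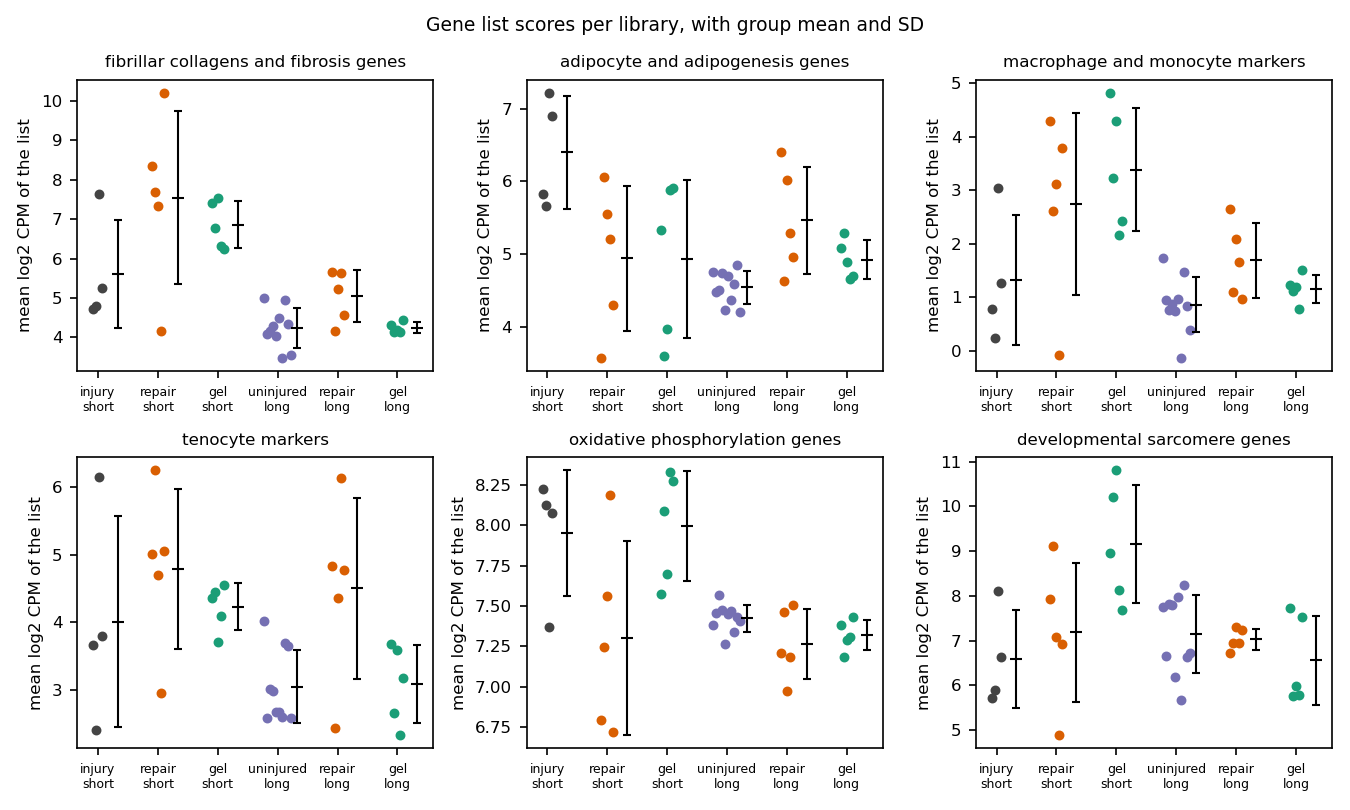
Mean log2 CPM of the genes of 6 lists in each library (points), by group, with the group mean and SD (bars). The collagen and fibrosis score of short-term repair spans the widest range, 7.55 ± 2.19 (SD, n = 5), against 6.86 ± 0.601 with the gel (SD, n = 5).

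In the long term, gel was compared with repair alone (5 against 5 libraries). Fibrillar collagens and fibrosis genes were lower with the gel (median log2 difference -0.73, 24 of 25 members below 0), as were tenocyte markers (-1.86, 7 of 7), basement membrane genes (-0.39, 14 of 14), adipocyte genes (-0.73, 14 of 15), matrix proteases (-0.38, 14 of 16), macrophage markers (-0.64, 11 of 11) and alternative macrophage genes (-0.56, 9 of 9). Fast fibre genes (0.54, 11 of 12 above 0), glycolysis genes (0.37, 17 of 20) and oxidative phosphorylation genes (0.15, 23 of 31) were higher. These were 10 of 26 lists by camera with its preset correlation. With an estimated correlation 0 passed, with an adjusted p of 0.593 for oxidative phosphorylation genes and 0.536 for the other 9. Adjusted over the list alone, 12 collagen and fibrosis genes and 6 tenocyte markers were lower, as were 2 adipocyte genes. The number of lists was 6 without repair replicate 1, and 14 without gel replicate 1, which lies apart from its group.

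Over 11605 genes edgeR called 0, with 1648 at an unadjusted p under 0.05 and a smallest adjusted p of 0.302. DESeq2 called 7 and limma voom with sample quality weights 0. The smallest p belonged to XBP1, a transcription factor of the unfolded protein response (1.14, SE 0.22), the transcription factor gene KLF5 (-1.91, SE 0.40), the secretoglobin gene SCGB1D1 (-2.33, SE 0.53), LOC108175684 (0.62, SE 0.15) and the tetraspanin gene TSPAN8 (-2.96, SE 0.69). XBP1 averaged 64.5 ± 20.9 CPM with the gel and 29.3 ± 2.82 CPM with repair alone (SD, n = 5 each). Of 20 panel genes 0 passed. Values below 0 were fitted for COL1A1 (-1.29, SE 0.45), COL3A1 (-0.50, SE 0.38), POSTN (-1.44, SE 0.48), DCN (-0.64, SE 0.29), PPARG (-0.995, SE 0.41), ADIPOQ (-0.88, SE 0.29), FABP4 (-1.37, SE 0.36) and MYH3 (-0.55, SE 0.27). Without repair replicate 1 COL3A1 was -0.157, DCN -0.416, PPARG -0.453 and ADIPOQ -0.568, without repair replicate 4 COL1A1 was -0.706, and without repair replicate 3 MYH3 was -0.365. The other 12 lay between -0.69 and 0.59.

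Repair alone was then compared with uninjured muscle in the long term (5 against 10 libraries). Of 11605 genes, 112 rose and 5 fell after repair by edgeR with the libraries taken as independent. With the animal as a block, by the animal codes of the files, edgeR called 0 genes, and limma voom with the animal as a random effect called 0, so the calls named here were lost once the animal was taken into account. The fitted log2 differences with the block stayed above 0, at 2.56 for LEP, 1.91 for CIDEA, 1.93 for THRSP, 1.38 for PPARG, 1.21 for FABP4, 2.23 for KERA and 2.95 for FMOD (adjusted p 0.561 each) and 1.41 for CHAD (0.651), and the adipocyte score was higher in the repaired muscle of 5 of 5 animals (mean 0.929). Adipocyte genes were among those that rose: 7 of 15 passed, including the leptin gene LEP (log2 difference 3.39, SE 0.54), the lipid droplet gene CIDEA (2.21, SE 0.41), the lipogenic gene THRSP (2.47, SE 0.46), the adipogenic regulator PPARG (1.78, SE 0.34) and the fatty acid binding protein gene FABP4 (1.56, SE 0.30). Tenocyte genes rose in 5 of 7, among them the proteoglycan genes KERA (2.92, SE 0.58), FMOD (3.74, SE 0.83) and CHAD (2.08, SE 0.49). Without repair replicate 4 FMOD was 1.74 and CHAD 0.65, neither of them past the threshold. FABP4 averaged 186 ± 141 CPM after repair (SD, n = 5) and 63.4 ± 10.0 CPM in uninjured muscle (SD, n = 10).

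In the same test without a block, 3 of 25 fibrillar collagen and fibrosis genes rose, COL12A1 (1.93, SE 0.40), COL11A1 (2.92, SE 0.66) and the collagen cross-linking enzyme LOX (1.43, SE 0.30). Without repair replicate 4 COL12A1 was 1.20 and COL11A1 1.28, neither of them past the threshold. Macrophage genes that rose were SPP1, which encodes osteopontin (2.42, SE 0.51), and GPNMB (1.98, SE 0.47). Single genes or pairs rose in other lists: the fibroblast gene DPT (1.11, SE 0.23), the protease gene CTSK (0.93, SE 0.20), the TGF-beta genes TGFBR2 (0.85, SE 0.17) and LTBP2 (1.22, SE 0.26), the cytokine gene IL18 (1.53, SE 0.33), the cartilage collagen gene COL2A1 (1.59, SE 0.35) and the Schwann cell cadherin gene CDH19 (1.41, SE 0.34). Without repair replicate 4, SPP1 was 1.53 and COL2A1 0.89, also short of it. Without repair replicate 1 or without repair replicate 3 edgeR called 0 genes, though the log2 differences moved less: with each library left out in turn the lowest were 2.34 for LEP, 1.85 for CIDEA, 1.96 for THRSP, 1.24 for PPARG, 1.16 for FABP4, 2.05 for KERA and 0.814 for DPT. Of the 15 fits with a library left out, COMMD6 no longer passed in 13 (it passed without repair replicate 2 or uninjured replicate 7), CDH19 in 12 (it passed without repair replicate 2, uninjured replicate 1 or uninjured replicate 6), CHAD in 11, GPNMB and COL11A1 in 10, FMOD in 9 and COL2A1 in 6. TRABD2B (1.85, SE 0.31) and TSPYL2 (0.55, SE 0.10) rose without overlap of the groups, and COMMD6 fell by 0.69 (SE 0.17), also without overlap. Of 20 panel genes 2 passed, PPARG and FABP4. COL1A1 (1.49, SE 0.37, adjusted p 0.0528) and ADIPOQ (0.97, SE 0.24, adjusted p 0.0561) missed the threshold, and COL3A1 (0.68, SE 0.32), PDGFRA (0.65, SE 0.23), DCN (0.77, SE 0.25), CD163 (1.23, SE 0.48), CSF1R (0.88, SE 0.38) and PAX7 (-0.52, SE 0.29) lay further from it. Without repair replicate 4 COL1A1 was 0.91, and without repair replicate 1 COL3A1 was 0.332, PDGFRA 0.34, CD163 0.401 and CSF1R 0.35. The other 10 lay between -0.19 and 0.94.

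By camera with its preset correlation 12 of 26 lists passed. Higher lists were adipocyte genes (median 0.97), tenocyte markers (1.67), collagens (0.74), macrophage markers (0.95), alternative macrophage genes (0.72), cartilage and bone genes (0.70), fibro-adipogenic markers (0.53), basement membrane genes (0.43), matrix proteases (0.32) and immediate early genes (0.32). Slow fibre genes (-0.53) and oxidative phosphorylation genes (-0.18) were lower. With an estimated correlation 0 passed, with an adjusted p of 0.0623 for adipocyte genes, 0.0717 for tenocyte markers, 0.131 for collagens and alternative macrophage genes, 0.132 for macrophage and basement membrane genes, 0.143 for cartilage and bone genes, 0.180 for fibro-adipogenic markers and proteases, 0.351 for oxidative phosphorylation genes, 0.490 for immediate early genes and 0.612 for slow fibre genes. Adjusted over the list alone, 16 collagen and fibrosis genes, 9 adipocyte genes, 8 macrophage markers, 8 basement membrane genes and 6 tenocyte markers were higher.

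The smallest edgeR adjusted p was 0.0109, and 1360 genes had an unadjusted p under 0.05. Without repair replicate 1 or without repair replicate 3 the count was 0. It was 62 without repair replicate 4, 185 without repair replicate 5, 319 without repair replicate 2, and 69, 71 and 63 without uninjured replicates 3, 4 and 10. DESeq2 called 234 genes and limma voom with sample quality weights 12.

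Gel-treated repair was compared with the same 10 uninjured muscles (5 against 10 libraries). Glycolysis and glycogen genes had a median log2 difference of 0.49 (19 of 20 above 0), fast fibre genes 0.44 (12 of 12), Schwann cell markers 0.27 (9 of 10) and adipocyte genes 0.18 (11 of 15). These 4 of 26 lists passed camera with its preset correlation, and 0 passed with an estimated one (adjusted p 0.868 for each of the 4). Adjusted over the list alone, 8 glycolysis genes were higher and 1 was lower. The number of lists was 9 without gel replicate 1, and 2 without gel replicate 2 or without gel replicate 5. One gene, LOC100009097, rose (3.62, SE 0.57), from 0.184 ± 0.194 CPM (SD, n = 10) to 2.31 ± 1.16 CPM (SD, n = 5). It falls outside the rule for named genes and was chosen after its values were seen.

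The call of LOC100009097 was lost with the animal as a block and without gel replicates 2, 3 or 4 or any of uninjured replicates 3 to 9, where edgeR called 0 genes, and in the fit of all 34 libraries. Its log2 difference stayed between 3.40 and 4.03 with libraries left out in turn, and it passed with the animal as a random effect. DESeq2 called 15, and 1606 genes had an unadjusted p under 0.05. Of 20 panel genes 0 passed. The fitted values were 0.78 (SE 0.36) for PPARG, 0.09 (SE 0.25) for ADIPOQ, 0.18 (SE 0.31) for FABP4, 0.20 (SE 0.38) for COL1A1, -0.50 (SE 0.42) for POSTN, 0.35 (SE 0.23) for PDGFRA, 0.13 (SE 0.25) for DCN, 0.54 (SE 0.52) for CD163 and 0.37 (SE 0.39) for CSF1R. Single libraries moved values this near 0: COL1A1 was 0.0396 and CSF1R 0.13 without gel replicate 1, FABP4 -1.47e-05 and DCN 0.0294 without gel replicate 2, ADIPOQ -0.069 without gel replicate 3, and POSTN -0.27 without uninjured replicate 1. The other 11 lay between -0.65 and 0.43.

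**Figure D3:**
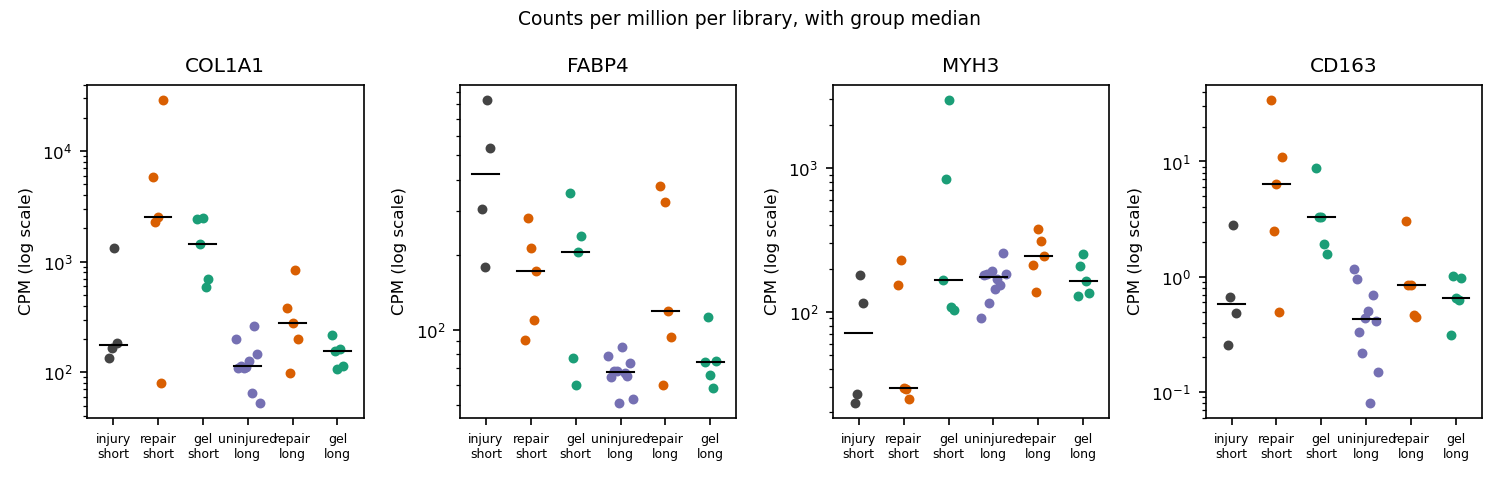
CPM of COL1A1, FABP4, MYH3 and CD163 in each library (points, log axis) with the group median (line). COL1A1 ranges from 80.35 to 29260 CPM in short-term repair and from 52.57 to 263.3 CPM in uninjured muscle. These values are scaled over all 34 libraries, and so differ from the CPM in the text, which are scaled within each term.

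Genes higher or lower in the mean of the repair and gel groups than in uninjured muscle were followed in gel against repair in the long term. Such a gene need not differ in both groups. The list planned for this held fewer than 5 genes in a direction, so the 100 genes with the smallest p in each direction were used, a choice made after seeing the data. The median log2 difference between gel and repair was -0.68 for the genes higher than uninjured, with 85 of 100 below 0 (camera p = 1.12e-07 at its preset correlation), and -0.05 for those lower than uninjured (camera p = 0.822). The first was lost with an estimated correlation (p = 0.236) and with the animal as a block (median -0.206, camera p = 0.746). Without repair replicate 1 the median was -0.266, and without gel replicate 1 it was -0.408. The lists were chosen on these same libraries and are not independent evidence of direction.

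The difference in gel effect between terms was tested over 12935 genes. It was -2.12 on the log2 scale for ATXN7L2 (edgeR adjusted p 0.00138) and 1.88 for XBP1 (adjusted p 0.0015), the 2 genes that passed, chosen after their values were seen. The fit of all 34 libraries shares its spread between terms. The common coefficient of variation between libraries was 0.352 in it, 0.445 in the short-term fit and 0.269 in the long-term fit. The shared fit may understate the short-term spread, and these adjusted p-values may then be too small. Developmental sarcomere (-1.69), slow fibre (-1.17), macrophage (-1.05), lymphocyte (-1.67), oxidative phosphorylation (-0.41) and citric acid cycle genes (-0.42) passed camera with its preset correlation. With an estimated correlation the adjusted p was 0.834 for macrophage markers, 0.626 for oxidative phosphorylation genes and 0.453 for the other 4. The gene count was 4 without short-term repair replicate 2 and 9 without short-term repair replicate 4.

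Repaired and gel-treated muscles together differed between terms in 8164 genes by edgeR, 3526 higher and 4638 lower in the long term. Fibrillar collagens and fibrosis genes fell in 26 of 26 members (median -3.05), macrophage markers in 17 of 17 (-2.81) and cell cycle genes in 22 of 24 (-2.92), while 20 of 28 citric acid cycle and fatty acid oxidation genes rose (0.76). By camera with its preset correlation 9 of 27 lists passed, 1 higher and 8 lower, 0 with an estimated correlation (adjusted p 0.742 for these 4) and 18 by fry. Ribosomal protein genes, chosen after their values were seen, moved about as far (median -3.34, 64 of 67 lower in the long term). The terms also differ in depth and in the form of the file headers, so term and processing cannot be told apart.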

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

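The tests of the swap, the wrong file, the library size of repair replicate 4, the slow fibre share, the lower muscle share and the rise without single repair libraries were chosen after the results were seen, as were the counts over 100 other splits. The tests of the library size of injury replicate 3, of another animal, of a few abundant genes and of splits that part the same animals were written before their results. A library was singled out where its gap to the nearest other library of its group exceeded a fixed share of the group's range. Chance gives this in about 1 in 20 groups if values are normally distributed. Of 438 groups tested 61 were singled out, where about 22 would be for independent normal values. Single genes were taken as CPM without logs, and the tests share libraries. The 22 is therefore no sound expectation here, and no excess over chance is claimed.

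Injury replicate 3 of the short term accounted for 12 of the 61 and repair replicate 4 for 4. Injury replicate 3 was the highest of its group for COL1A1 (1473 CPM), COL3A1 (3514 CPM), POSTN (445 CPM), TGFB1 (11.2 CPM), PAX7 (6.77 CPM), CHRNA1 (46.4 CPM), CD163 (3.11 CPM), CSF1R (28.2 CPM), PECAM1 (110 CPM) and MKI67 (1.61 CPM). It was the lowest for TRIM63 (96.5 CPM) and for the glycolysis score (9.06 mean log2 CPM). Repair replicate 4 was the lowest of its group for fibro-adipogenic markers (4.28), basement membrane genes (5.01) and neutrophil and mast cell markers (-2.43, all mean log2 CPM), and for the number of genes detected (13978). A swap of these 2 labels was tested by correlations with the remaining libraries of each group: injury replicate 3 lay closer to repair by 0.0095, less than the SD of the correlations (0.0206), and repair replicate 4 closer to injury by 0.0743. The bound at that SD was set after the value was seen, so a swap cannot be told apart from no swap. Library size is argued against for repair replicate 4, whose total, 30.1 M counts (30074147), lay inside the range of the other repair libraries. Injury replicate 3 had the lowest total of the 14 libraries (26904529), but with the short-term libraries thinned to that total it still lay at least 33.6 from the nearest other injury library on the first component over 10 thinnings, where the others span 12 without thinning. A wrong file for injury replicate 3 alone cannot be told apart from none: of 2 breaks in the order of column heading numbers against animal codes, 1 ends without either of 2 libraries, injury replicates 3 and 4. The heading number of injury replicate 3 was 8, between those of repair replicate 1 (9) and gel replicate 1 (7). Those of injury replicates 1, 2 and 4 were 16, 14 and 11. A biological difference between animals stays open and untested.

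Gel replicate 1 of the long term had 36.4% of genes over 2-fold from the mean of its group, against 2.22% to 5.89% in the other 19 long-term libraries. It was the highest of its group for denervation genes (5.12 mean log2 CPM), TGFB1 (11.1 CPM), MYOD1 (30.9 CPM), CHRNA1 (45.9 CPM), XBP1 (101 CPM) and the share of its most abundant gene (10.1%), and the lowest for DCN (129 CPM) and PPARGC1A (7.92 CPM). A few abundant genes are argued against, since the share was 36.5% without the 10 most abundant ones, and so is a higher share of slow fibres, since libraries with as high a slow fibre score reached at most 5.74%. Those libraries were all uninjured, and each was measured from its own group. The one at 5.74%, uninjured replicate 1, scored 11.71 against a group mean of 10.55, and gel replicate 1 scored 11.17 against 9.93. Whether it is a library of another animal is not decided. Over 82 genes that rank alike in both muscles of the other animals, the uninjured library of its own code ranked 9 of 10. A library this far from all others might rank low for any reason. Another animal alone is argued against as the source of the distance. The codes within each group differ, yet the other 19 libraries reached at most 5.89%. A biological difference in this animal was not tested.

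The third pattern was the higher adipocyte and tenocyte genes after repair in the long term. A lower share of muscle fibres alone was weighed by the endothelial and pericyte scores, on the untested assumption that it would raise markers of other cell types alike. Within the 5 animals the adipocyte score was higher by a mean of 0.929 after repair (5 of 5 above 0, 95% t interval -0.061 to 1.92). The endothelial score was higher by 0.0512 and the pericyte score by 0.0231, with upper 95% t limits of 0.173 and 0.284. These values cannot decide, since the adipocyte interval holds both smaller rises. The tenocyte score (4 of 5 above 0, mean 1.41) was not compared with them. With the libraries taken as independent the adipocyte score rose by 0.898 more than the endothelial score (exact permutation p = 0.000666), though within the animals the interval of this difference spanned 0 (-0.0686 to 1.82). The tenocyte median log2 difference did not fall without repair replicates 1 and 3 (2, against 1.67 with them). The exact permutation p for the score was 0.049 over libraries taken as independent. Of the 3 animals left 2 were above 0, with a 95% t interval of -3.14 to 6.17, so whether replicates 1 and 3 carry the rise is not decided. For adipocyte genes the median was 0.348 without repair replicates 1 and 3 (0.97 with them), and for tenocyte markers 0.89 without repair replicate 4, each lower but above 0 (exact permutation p = 0.0245 and 0.032). In this pair of cases a rise carried by these libraries cannot be told apart from one shared by the group, since part of the rise went and part stayed. Repair replicate 1 was the highest of its group for LEP (17.4 CPM) and CD163 (2.97 CPM), and repair replicate 4 for COL11A1 (23.7 CPM), SPP1 (13.8 CPM), FMOD (236 CPM), CHAD (47.5 CPM) and COL2A1 (63.6 CPM). Tendon or fat carried into single muscle pieces, or an effect of repair in some animals, may each give such values, and neither was tested beyond these counts.

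Other single libraries in the short term were repair replicate 5, highest for COL1A1 (31720 CPM) and COL3A1 (31500 CPM) and lowest for PPARGC1A (3.68 CPM). Gel replicate 3 was highest for MYH3 (3303 CPM), MYOD1 (103.5 CPM), CHRNA1 (126 CPM) and immediate early genes (5.68 mean log2 CPM). Gel replicate 1 was highest for CD163 (9.56 CPM), repair replicate 1 for ARG1 (8.95 CPM), repair replicate 2 for ATXN7L2 (20.8 CPM), repair replicate 3 for TRIM63 (367 CPM) and injury replicate 1 for FUOM (30.4 CPM). Injury replicate 2 was lowest for PDE4B (13.6 CPM).

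In the long term, repair replicate 3 was lowest for fast fibre genes (11.1 mean log2 CPM) and glycolysis genes (9.16), and repair replicate 5 highest for TRIM63 (244 CPM). Gel replicate 5 was highest for interferon response genes (3.35 mean log2 CPM), POSTN (12.9 CPM), COMMD6 (5.29 CPM) and CDH19 (22.7 CPM), and gel replicate 2 for FABP4 (106 CPM) and DPT (54.5 CPM). Among uninjured muscles, the highest were replicate 10 for interferon response genes (3.17 mean log2 CPM), replicate 4 for MYOD1 (22 CPM) and for the share of the most abundant gene (7.21%), replicate 9 for TRIM63 (253.5 CPM), replicate 7 for PPARGC1A (113 CPM), replicate 1 for CTSK (19.9 CPM) and KERA (2.34 CPM), and replicate 2 for LOC100009097 (0.657 CPM).

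The effect of the gel differed between terms for ATXN7L2 (-2.12) and XBP1 (1.88), by the interaction term of the edgeR test. That fit shares its spread between terms. By camera with its preset correlation it differed for developmental sarcomere genes (-1.69), slow fibre genes (-1.17), macrophage markers (-1.05), lymphocyte markers (-1.67), oxidative phosphorylation genes (-0.41) and citric acid cycle genes (-0.42). By fry, or with an estimated correlation, 0 lists passed, the adjusted p of the latter being 0.834 for macrophage markers, 0.626 for oxidative phosphorylation genes and 0.453 for the other 4.

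Other splits of the same samples into groups of the same sizes, 100 for each result, were used to ask whether chance can be excluded. It can be for the 8164 genes between terms only among these splits (1 split with as many, the real one included, highest other 4442). That is the smallest share 100 splits allow, and it was not corrected for the number of results split. Nor does it part term from processing, which cannot be told apart. For the 2 genes of the difference in gel effect 4 splits gave as many, the real one included (highest other 10). That share was not corrected for the number of results split, so chance cannot be excluded for these 2 genes. For the 117 genes of repair against uninjured muscle chance can be excluded only among these splits, which ignore the animals, and without such a correction (1 split, highest other 3). It cannot be among those that part the same animals (2 of 32, highest other 165, median of the others 0). The split with 165 genes exchanged only repair replicate 2 and uninjured replicate 2, so it is close to the real grouping. With the animal as a block 0 genes passed. As many as the 19 lists of repair against injury, by camera with its preset correlation, came from 4 splits (highest other 21, median 13). That share was likewise not corrected, so chance cannot be excluded for this count. With an estimated correlation, with fry or with the permutation test 0 lists passed. A count of 0 is reached by any split, so the splits say nothing on the gene counts of 0 in gel against repair in the short term (100 splits; highest other 1), repair against injury (100; 5734), gel against injury (100; 0) and gel against repair in the long term (100; 16). Chance cannot be excluded for the 1 gene of gel against uninjured muscle (9; 224). The split with 5734 genes exchanged repair replicate 4 and injury replicate 3 and points to a structure of the samples. The one with 224 set uninjured replicates 1, 3, 6, 8 and 10 against the gel and the other uninjured libraries, a structure whose source was not tested. Nor can chance be excluded for the 10 lists of gel against repair in the short term (75; 21), the 18 of gel against injury (12; 21), the 10 of gel against repair in the long term (19; 14), the 12 of repair against uninjured muscle (24; 18), the 4 of gel against uninjured muscle (67; 16), or the median of the genes higher in treated muscle (12; 0.902).

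Since the animal codes pair the long-term samples, the 32 splits that part the same animals were run too. As many genes as in repair against uninjured muscle came from 2 of the 32, the real one included. The other, with 165, exchanged only repair replicate 2 and uninjured replicate 2. As many lists came from 14 of the 32 (16). For gel against uninjured muscle these were 3 (8) and 16 (10). Among splits of this kind chance cannot be excluded for any of the 4 results.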

How the results depend on the processing

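Alternatives that left out libraries lying apart, that used the animal as a random effect, or that concern the top-ranked treated genes were chosen after seeing the data. The cause of the changes below was not tested, except that leaving out samples leaves fewer samples. DESeq2 called 127 genes for gel against repair in the short term, 242 for repair against injury, 788 for gel against injury, 7 for gel against repair in the long term, 234 for repair against uninjured muscle, 15 for gel against uninjured muscle and 28 for the difference in gel effect. Limma voom with sample quality weights called 3, 4692, 3776, 12 (repair against uninjured muscle) and 5 (difference in gel effect). All 34 samples in one fit gave 93, 626, 1085, 1, 9 and 0 genes for the 6 comparisons in that order. Only the groups compared gave 7 for gel against injury and 63 for repair against uninjured muscle. Without injury replicate 3 and repair replicate 4 the short-term counts were 13, 4556 and 2577, and with gel replicate 1 left out too the difference in gel effect had 10.

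With each replicate left out in turn, gene counts ranged from 0 to 2, 0 to 34, 0 to 382, 0 to 0, 0 to 319 and 0 to 1 in the 6 comparisons, 2 to 9 for the difference in gel effect and 7717 to 8634 between terms. Numbers of lists ranged from 10 to 15, 18 to 21, 14 to 18, 6 to 14, 10 to 13 and 2 to 9.

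With an estimated correlation and with the exact permutation test 0 lists passed in each of the 6 comparisons, and with fry 0, except 6 for repair against uninjured muscle. No filter on low counts gave 7 lists for gel against uninjured muscle. With the replicate block by animal 0 genes passed for repair and 0 for gel against uninjured muscle. As a random effect the animal left 0 for repair. Title numbers do not pair the samples, with correlations above 0.1 in 0 of 5, 2 of 5, 1 of 4 and 2 of 4 pairs. As a block they gave 157 genes for gel against injury, and 0 for repair against injury.

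Repair and gel against the same uninjured muscles correlated at r = 0.294 across genes, which are not independent replicates. Unchanged groups simulated against those controls gave 0.336, controls split between the comparisons 0.15, and residuals of the real libraries reassigned at random 0.33 (-0.13 to 0.684). These values, and those for the covariance that follow, ignore the pairing by animal code. The covariance was 0.032, against 0.0215 simulated and 0.0219 reassigned (-0.00718 to 0.0674). Against the same injured muscles r was 0.768, with 0.556 simulated, 0.474 with split controls and 0.501 with reassigned residuals. The interval of the last, -0.173 to 0.869, holds the observed value. The covariance was 0.417 against 0.129 simulated and 0.118 reassigned (-0.0509 to 0.346), so it lay above its interval while r lay inside. The reassignments thus do not decide whether the likeness goes beyond the shared controls. The calls shared were 0 in each direction, where independent lists give 0.00965 higher calls in the long term.

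The median of the genes higher in treated muscle was -0.206 with the animal block (p = 0.746) and -0.975 to -0.266 with replicates left out, and its p with an estimated correlation was 0.236. That of the genes lower in treated muscle turned to 0.0488 with 50 genes, 0.169 without repair replicate 2, 0.0504 without repair replicate 5 and 0.0633 without gel replicate 1, within a range of -0.155 to 0.169 with replicates left out. ADIPOQ turned to 0.103 with voom in repair against injury, and in gel against uninjured muscle to -0.0101 without gel replicate 2 and -0.069 without gel replicate 3, where FABP4 was -1.47e-05 without gel replicate 2. With replicates left out these ranged from -0.069 to 0.241 for ADIPOQ and from -1.47e-05 to 0.268 for FABP4. Of the values of single genes under alternatives, 1950 kept direction and side of the threshold, 145 newly passed, 230 no longer passed and 4 turned. In the short term, simulated 2-fold changes were recovered in 17% to 22% of genes, which limits what counts of 0 can show.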

Other observations

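All values here were chosen after the data were seen. Ribosomal protein genes, which encode the protein part of ribosomes, differed between terms in the repaired and gel-treated muscles: of 67 tested, 64 were lower in the long term, 64 fell and 2 rose by edgeR, with a median log2 difference of -3.34. The terms differ in depth and file headers, so no explanation was tested.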
